A study of Cavia porcellus with 12 samples.

How the data were processed

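The authors' deposited counts were used as they stand, as raw gene counts for 12 libraries and 18,933 Ensembl guinea pig genes. Per the submitters' processing notes the upstream tools were FastQC, fastp, STAR 2.7.11a, featureCounts and DESeq2 1.38, with no roles or settings given. Per the labels' protocols the RNA came from guinea pig cartilage with an RNeasy Mini kit, poly(A) RNA was selected and the libraries were strand-specific, and both a TruSeq Stranded mRNA and a NEBNext Ultra II Directional kit are named. The genome build and annotation release were not given in the sources used here. The values were whole numbers with totals of 77,813,795 to 101,835,258, and the smallest gene total was 6, so genes with almost no counts appear to have been left out upstream. A median of 18470 genes per library had a count.

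Library totals are sums of the count table. Treatments, sexes and dose labels came from the sample labels, and the unit behind 1M and 2M is not spelled out in them. Over 66 pairs of libraries the smallest chi-square per degree of freedom was 93.9, where counting alone would give 1, so every pair differed by more than counting. Symbols came from the deposited table (5,918 genes; 12 symbols on 2 rows), and 5,898 Entrez identifiers were matched to a RefSeq gene table of the assembly mCavPor4.1, used only for current names. For a symbol on 2 rows the row of the higher mean count was used.

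Genes were kept by filterByExpr on treatment with a minimum count of 10, leaving 16,928 genes, 5,412 with a symbol. Counts were scaled by TMM and fitted with edgeR 4.0.16 quasi-likelihood (robust, with dispersions by its newer method) on treatment and sex over all 12 libraries, in R 4.3.3. Contrasts were 1M against DPBS, 2M against DPBS, 2M against 1M, the mean of the doses against DPBS and female against male, and a second model with the 5 treatment and sex groups gave the interaction of dose and sex. The threshold was a Benjamini-Hochberg adjusted p of 0.05 within each contrast. SE is the absolute log2 fold change over the square root of F, and log2 CPM values used a prior count of 2.

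The design, the 39 gene lists and the naming rule were fixed before the data were examined. The rule names, per contrast and direction, up to 10 genes with a symbol past the threshold at a mean log2 CPM of at least 1, filled up to 5 by the smallest p, and 12 of 29 genes chosen in advance that had a row. The 31 lists with at least 5 tested members were tested by camera on voom values with a preset correlation of 0.01 and Benjamini-Hochberg over the lists of a contrast. Alternatives were camera with an estimated correlation and fry. For single members, p was also adjusted over the list alone.

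Other fits were DESeq2 1.42.0 (Wald test), limma 3.58.1 voom with quality weights, DESeq2 size factors, total-count scaling, minimum count 50, no filter, no sex term, male libraries only, groups compared only, each library left out in turn, and a threshold of 0.1. Chosen after results were seen were a marrow score or a bone score as a term, the removal of the library with the lowest haemoglobin in each treatment, and the permutations of list scores. Scores were mean log2 CPM of a list in a library. Exact permutations ran over all splits of the libraries, and correlations used 100000 resamples. The libraries of each contrast were also regrouped into groups of the same sizes, to count how often as many genes or lists passed.

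A self-test simulated counts for 1M against DPBS over 16,740 genes from the fitted means and dispersions, with log2 shifts of 0.5, 1, 2 and 3 in chosen genes and 1 shifted list. At a shift of 0.5 edgeR recovered 2 of 49 genes and DESeq2 9. The shifted list of bone-cell genes was recovered with a median of -0.91, and it was the 1 list of 31 past the threshold. Genes were drawn independently, so the self-test does not show how camera acts on lists whose members vary together. In the real 1M contrast the estimated correlation of that list was 0.61. Other groupings of the real 1M and DPBS libraries passed a median of 8.5 lists.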

Results

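The deposited counts covered 18,933 guinea pig genes in 12 cartilage libraries taken 6 months after an injection of DPBS or PLX-PAD cells into the knee. There were 4 libraries each of DPBS, PLX-PAD 1M and PLX-PAD 2M. Library totals ran from 77,813,795 to 101,835,258 counts. The DPBS libraries were all male, while 1M had 2 male and 2 female libraries and 2M had 3 male and 1 female. Only 5,918 genes carried a symbol, and the 13,015 without one held 57.18% of the counts, so the genes named here come from the smaller part of the table. The replicates are not said to be separate animals, so each p measures the spread between these samples, which may be partly technical.

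Values are log2 fold changes ± SE from the 12 libraries unless given as CPM (mean ± SD, n = 4), and every test was two-sided. The fold changes are adjusted for sex and the CPM means are not, so a pair of CPM means can differ more or less than its fold change. Since no DPBS library was female, the sex term was estimated from the treated libraries alone. The model takes the sex difference to be the same without treatment, which could not be tested. A bare value in parentheses after a gene's change is its edgeR adjusted p, and after a list's median it is the camera adjusted p. The treatment and sex model, the gene lists, the comparisons and the rule for naming genes were fixed before the data were examined. The members counted for a list are only its genes with a row under their symbol. These were 11 of 28 for cartilage matrix, 13 of 29 for proteases and 7 of 23 for neutrophil markers. Members of a list that are named for passing when adjusted over the list alone were chosen after their values were seen.

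Blood and cartilage genes varied strongly between libraries of the same treatment. Haemoglobin alpha (LOC100712878), a red cell gene, took 2.36 ± 0.75% of the counts in DPBS, 3.51 ± 1.82% in 1M and 2.75 ± 0.84% in 2M. Against DPBS the exact permutation p was 0.286 for 1M and 0.514 for 2M. Col2a1, the main collagen of cartilage, ranged from 24975 ± 11851 CPM in DPBS to 8569 ± 6854 CPM in 1M and 15023 ± 12916 CPM in 2M. Over the 12 libraries the neutrophil score followed the erythroid score (Pearson r = 0.891, permutation p = 6e-05, adjusted 0.00012). The Spearman rho was 0.846 (permutation p = 0.0011, adjusted 0.0017), and without the 2 farthest libraries r was 0.731. It ran against the cartilage matrix score (r = -0.859, permutation p = 0.00042, and rho = -0.860, permutation p = 0.00063; r = -0.824 without the 2 farthest), these being 2 of 6 relations tested with Benjamini-Hochberg adjustment. The neutrophil score also followed the proliferation score (r = 0.941, permutation p = 3e-05; rho = 0.930, permutation p = 6e-05; r = 0.892 without the 2 farthest).

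In 2M against DPBS, the matrix-degrading protease list fell (median -1.10, camera adjusted p = 2.3e-10, adjusted p = 0.214 with an estimated correlation). The single genes that passed the test all lacked a symbol, so the named genes are given with their values. Ctsk, the collagen-cleaving cathepsin K of osteoclasts, stood at 1234 ± 445 CPM in DPBS and 357 ± 77.4 CPM in 2M, a log2 change of -1.67 ± 0.26 (edgeR quasi-likelihood with Benjamini-Hochberg, adjusted p = 0.0962). Atp6v0d2, a subunit of the osteoclast proton pump, had -1.74 ± 0.25 (40.42 ± 16.77 to 11.02 ± 1.726 CPM, adjusted p = 0.0886). Lamb1, a laminin chain of basement membranes, had -0.91 ± 0.12 (102.3 ± 13.9 to 50.7 ± 7.57 CPM, adjusted p = 0.0519). The collagenase Mmp13, which cleaves type II collagen, had -1.40 ± 0.30 (336 ± 156 to 116 ± 31.9 CPM, adjusted p = 0.193). The aggrecanase Adamts4 had -1.77 ± 0.36 (22.5 ± 12.8 to 5.68 ± 2.51 CPM, adjusted p = 0.177).

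By edgeR quasi-likelihood with Benjamini-Hochberg, 6 of 16,928 genes passed an adjusted p of 0.05 in 2M against DPBS, all lower and none with a symbol. The count was 0 without a sex term, in males only and when any 1 of 10 of the 12 libraries was left out. At an unadjusted p under 0.05 there were 1,166 genes, 271 higher and 895 lower, where 846.4 would be expected by chance. Against that same number, 1M against DPBS (1,283) and the mean of the doses (1,604) lay above. Below it lay 2M against 1M (252), females against males (636) and the interaction of dose and sex (394). Such a count alone therefore does not show a change. DESeq2 called 283 genes (25 higher) and voom with quality weights 394 (42 higher). In the self-test no gene was shifted in 2M, and there DESeq2 called 39 of 16,740 genes against DPBS, edgeR 0 and voom with quality weights 0. Among the 6, ENSCPOG00000011143 fell (-2.29 ± 0.27, adjusted p = 0.0422) and ENSCPOG00000008661 fell (-1.14 ± 0.14, adjusted p = 0.0422; 80.5 ± 14.1 to 34.3 ± 5.83 CPM). The other named genes with the smallest p did not pass. Below 0 were S1pr1, a receptor for sphingosine-1-phosphate, at -0.50 ± 0.08 (adjusted p = 0.0962) and Prdm1, a transcriptional repressor, at -0.98 ± 0.16 (15.3 ± 3.40 to 7.66 ± 0.65 CPM, adjusted p = 0.0962). Olfm1, a secreted olfactomedin, had 0.59 ± 0.09 (128 ± 10.8 to 194 ± 9.36 CPM, adjusted p = 0.0962). Also above 0 were Hk2, the hexokinase that starts glycolysis, at 0.48 ± 0.11 (0.208), Rap1gap at 0.83 ± 0.19 (0.210), Arhgef1 at 0.51 ± 0.12 (0.220) and Hprt1 at 0.30 ± 0.08 (0.304).

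In the protease list 12 of 13 members were lower in 2M (fry adjusted p = 0.0413). Over its 22 alternatives the camera adjusted p ran from 4.3e-12 to 0.214 and 21 stayed under 0.05. Adjusted over the list alone, 8 members were lower, among them Adamts4, Ctsk, Mmp13 and Mmp14 at -1.11 ± 0.34 (585 ± 195 to 258 ± 91.6 CPM). The others were Mmp11 at -1.10 ± 0.31, Adamts2 at -0.98 ± 0.31, Adamts9 at -0.55 ± 0.17 and Hyal2 at -0.44 ± 0.15. Mmp8, the neutrophil collagenase, was the member above 0, at 0.36 ± 0.53. The stromelysin Mmp3 had -1.38 ± 0.74 (36.0 ± 34.9 to 14.5 ± 8.18 CPM, edgeR quasi-likelihood with Benjamini-Hochberg, adjusted p = 0.831), and -0.42 without DPBS 4. The list median without that library was -0.73.

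**Figure D1:**
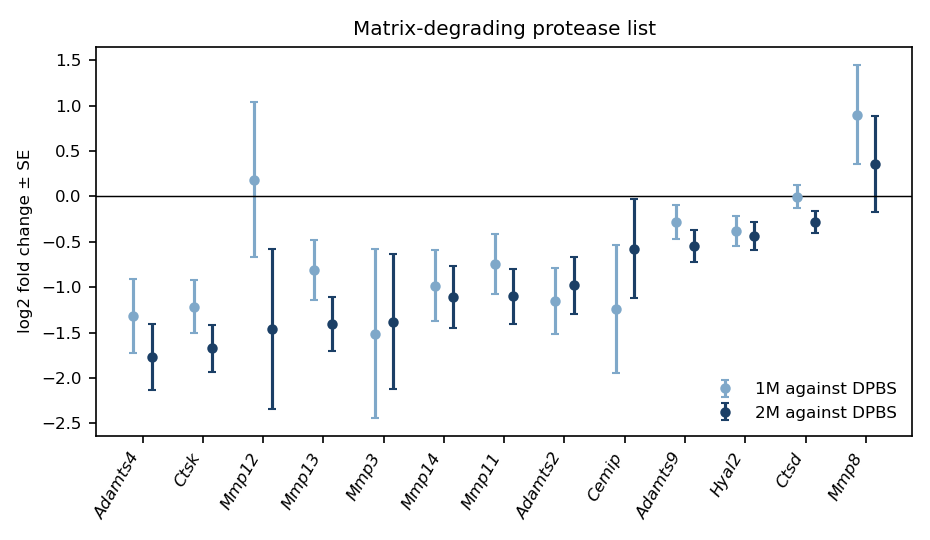
Log2 fold changes ± SE of the 13 tested members of the matrix-degrading protease list in 1M and 2M PLX-PAD against DPBS (4 libraries per treatment). Most members lie below 0 at both doses, and Mmp8 lies above it.

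Of 31 lists tested by camera, 8 passed in 2M against DPBS, 6 lower and 2 higher; with an estimated correlation 0 passed, and fry passed 1. Osteoblast and osteocyte markers fell (median -0.64, camera adjusted p = 0.000649, adjusted p = 0.698 with an estimated correlation). Adjusted over the list alone 5 of its members were lower: the osteocyte peptidase Phex at -0.80 ± 0.16 (28.6 ± 3.98 to 16.5 ± 1.89 CPM), Dmp1 at -0.90 ± 0.31, Bmp3 at -0.48 ± 0.15 and the osteoclast-inducing cytokine Tnfsf11 at -1.13 ± 0.38. The remaining member was Ifitm5 at -1.31 ± 0.37 (35.68 ± 9.862 to 14.02 ± 5.74 CPM). Sost, an osteocyte gene of the same list, had 0.60 ± 0.46. Growth factors fell (-0.54, camera adjusted p = 0.000649, adjusted p = 0.698 with an estimated correlation). Past when adjusted over the list alone were 3 of them, Pdgfb at -0.59 ± 0.10, its receptor Pdgfrb at -0.56 ± 0.13 and Igf1 at -0.95 ± 0.21 (85.5 ± 27.4 to 40.5 ± 8.48 CPM). The list of fibrous collagen and fibrosis genes fell with 6 of 6 members lower (median -0.84, camera adjusted p = 0.00485, adjusted p = 0.698 with an estimated correlation). Only 6 of its 27 genes had a row: Col5a2, Col12a1, Col14a1, Fn1, Tnc and Bgn. Type I and III collagen genes had no row under their symbols. Col12a1 at -1.37 ± 0.33 was the 1 member past when adjusted over the list alone. Endothelial and mural markers fell (median -0.38, camera adjusted p = 0.000743, adjusted p = 0.698 with an estimated correlation), 1 of them, Pdgfrb, adjusted over the list alone.

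The anti-inflammatory list fell with 5 of 5 members lower (median -0.51, camera adjusted p = 0.00894, adjusted p = 0.698 with an estimated correlation), 0 of them adjusted over the list alone. The median ran from -0.84 (without 2M male 2) to -0.25 (without DPBS 4). Il18bp, which binds interleukin-18, had -0.76 ± 0.24. Neutrophil and marrow myeloid markers rose with 7 of 7 members higher (median 0.62, camera adjusted p = 0.0263, adjusted p = 0.870 with an estimated correlation), 0 of them adjusted over the list alone. The granule enzyme Mpo had 0.46 ± 0.51 and Csf3r, the receptor for granulocyte colony-stimulating factor, 0.62 ± 0.45. Hypoxia and glycolysis genes rose with 14 of 15 members higher (median 0.18, camera adjusted p = 0.0313, adjusted p = 0.870 with an estimated correlation), 1 of them, Hk2, adjusted over the list alone. This list passed in 8 of 12 fits with 1 library left out, and without 2M male 2 its median was -0.06, below 0. The neutrophil list passed in 9 of the 12, with medians from 0.41 (without 2M male 1) to 0.88 (without 2M male 2).

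Cartilage matrix genes did not pass in 2M against DPBS (median 0.16, camera adjusted p = 0.895). By edgeR quasi-likelihood with Benjamini-Hochberg, Col2a1 had -0.72 ± 0.72 (adjusted p = 0.911), the proteoglycan core Acan 0.16 ± 0.66 (0.964), Comp 0.67 ± 0.67 (0.911) and the hypertrophy collagen Col10a1 0.40 ± 0.68 (0.937). The inflammatory list did not pass either (median -0.17, camera adjusted p = 0.166). In it the cytokines Il1b at 0.58 ± 0.46 (12.9 ± 2.49 to 19.0 ± 5.22 CPM, adjusted p = 0.897) and Tnf at 0.28 ± 0.34 (0.927) lay above 0. Lif at -1.58 ± 0.37 was lower when adjusted over the list alone. Nos2, which makes nitric oxide, had 0.60 ± 0.86 (0.933) and Vegfa, a growth factor for vessels, 0.12 ± 0.62 (0.968). Without 2M male 2 the values were -1.57 for Col2a1, -0.60 for Acan, -0.08 for Comp, -0.35 for Nos2 and -0.38 for Vegfa. Adipocyte markers (median 0.12, camera adjusted p = 0.188), skeletal muscle markers (1.12, 0.0982), proliferation genes (0.25, 0.121) and WNT genes (-0.21, 0.259) did not pass. The WNT target Ccn4 at -1.83 ± 0.41 was lower when adjusted over the list alone.

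Interferon-stimulated genes (0.26, 0.307), erythroid markers (0.20, 0.307), glycosaminoglycan synthesis (-0.13, 0.121), TGF-beta and BMP genes (-0.18, 0.159) and senescence genes (-0.27, 0.332) did not pass in 2M either.

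**Figure D2:**
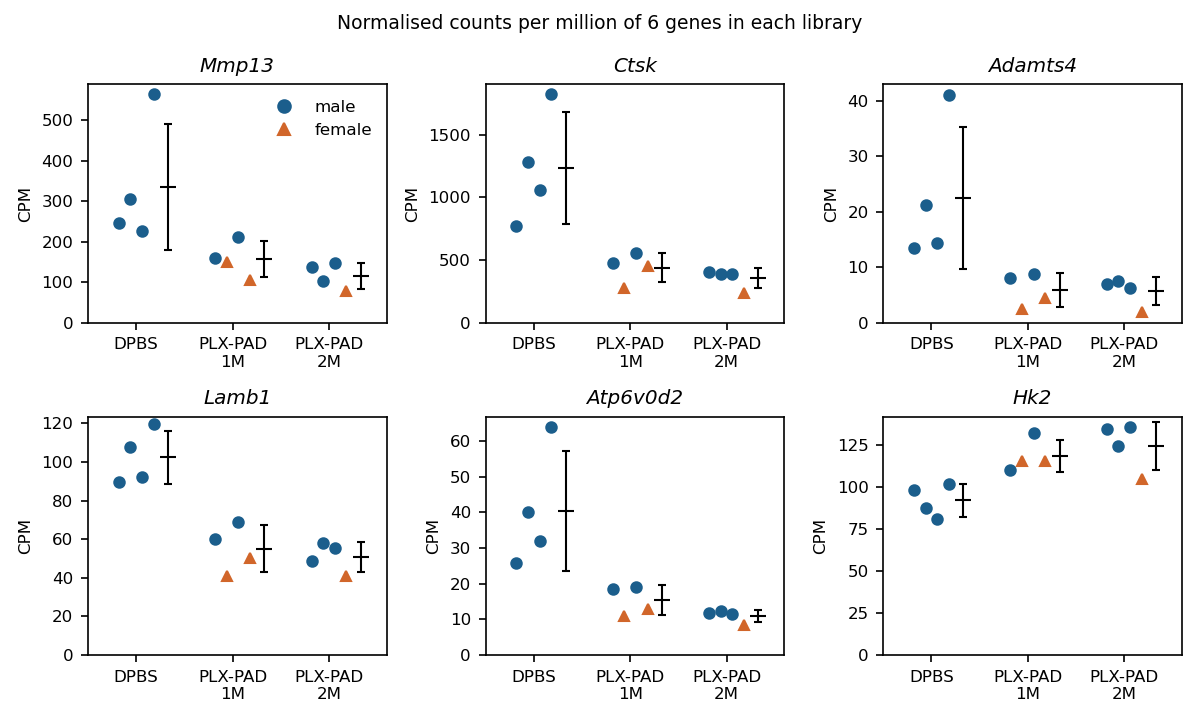
Normalised CPM of 6 genes in each library by treatment and sex, with mean ± SD (n = 4 per treatment). The 8 treated libraries lie below the 4 DPBS libraries for Mmp13, Ctsk, Adamts4, Lamb1 and Atp6v0d2 and above them for Hk2.

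In 1M against DPBS, the list of fat-cell genes was higher. Lists of proteases, of bone-cell genes and of fibrous collagen and fibrosis genes were lower. Each of these lists had adjusted p = 0.592 with an estimated correlation, and 0 single genes passed the test. Cldn1, a tight-junction protein, had 1.14 ± 0.21 (2.61 ± 0.55 to 5.88 ± 0.62 CPM, edgeR quasi-likelihood with Benjamini-Hochberg, adjusted p = 0.303), and G0s2, an inhibitor of fat breakdown, had 1.07 ± 0.24 (0.484). Phex had -1.05 ± 0.19 (0.287), and the kinase Pik3c2b, which phosphorylates membrane lipids, had -0.64 ± 0.10 (0.228). Sgms2, which makes sphingomyelin, had -0.78 ± 0.13 (0.238), the phosphatase Synj2 -0.71 ± 0.13 (0.303) and the lipase Lipc -1.08 ± 0.20 (0.327). Above 0 were also Enosf1 at 0.68 ± 0.16 (0.488), Hk2 at 0.45 ± 0.12 (92.0 ± 9.75 to 118 ± 9.66 CPM, 0.539) and Rap1gap at 0.77 ± 0.21 (0.539).

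By edgeR quasi-likelihood with Benjamini-Hochberg, 0 of 16,928 genes passed in 1M against DPBS (smallest adjusted p = 0.1021), with 1,283 genes at an unadjusted p under 0.05 (478 higher, 805 lower). DESeq2 called 161 genes (30 higher) and voom with quality weights 3,093 (914 higher). In 4 of 35 groupings of the same libraries voom called as many (highest other 6,430). Voom gave 1M female 2 a weight of 0.0891, the lowest of the 12. In counts simulated for 1M against DPBS, edgeR recovered 10 of 50 genes shifted by a log2 of 1, 33 of 49 shifted by 2 and 44 of 50 shifted by 3. It called 2 of 16,534 unchanged genes. DESeq2 recovered 23, 40 and 48 of those shifted genes and called 73 unchanged ones.

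Camera passed 15 of 31 lists in 1M against DPBS, 4 higher and 11 lower; with an estimated correlation 0 passed, and fry passed 0. The adipocyte list rose most, with 7 of 7 members higher (median 1.34, camera adjusted p = 9.5e-07, adjusted p = 0.592 with an estimated correlation). Adjusted over the list alone 5 members were higher. The lipid-droplet coat Plin1 had 2.29 ± 0.89 (7.77 ± 9.02 to 44.0 ± 24.2 CPM) and the adipokine Adipoq 1.42 ± 0.51 (115 ± 72.0 to 263 ± 84.2 CPM). With them stood the glycerol channel Aqp7 at 1.34 ± 0.49, the lipase Lipe at 1.27 ± 0.38 and Dgat2, which makes triglycerides, at 1.23 ± 0.48. Over its 21 alternatives the adjusted p ran from 8.8e-11 to 0.592. Without 1M male 2 and 1M female 2, whose library numbers 49 and 50 stand apart from the others, the median was 1.41. Neutrophil and marrow myeloid markers rose (median 0.80, camera adjusted p = 0.00877, adjusted p = 0.718 with an estimated correlation), 0 of them adjusted over the list alone. The granulocyte factor Cebpe had 0.98 ± 0.48 and Mpo 0.86 ± 0.53. Proliferation genes rose with 14 of 14 members higher (median 0.55, camera adjusted p = 0.0253, adjusted p = 0.793 with an estimated correlation), 0 of them adjusted over the list alone. Their median was -0.11 with the marrow score as a term, and they passed in 8 of 12 fits with 1 library left out, at 0.35 without 1M male 2. Cytosolic ribosomal proteins rose with 18 of 18 members higher (median 0.12, camera adjusted p = 0.00158, adjusted p = 0.592 with an estimated correlation), again 0 adjusted over the list alone.

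The matrix-degrading protease list fell in 1M with 11 of 13 members lower (median -0.81, camera adjusted p = 0.000217, adjusted p = 0.592 with an estimated correlation). Adjusted over the list alone 3 members were lower, Adamts4 at -1.32 ± 0.41 (22.5 ± 12.8 to 5.90 ± 3.02 CPM), Ctsk at -1.21 ± 0.29 (1234 ± 445 to 440 ± 115 CPM) and Adamts2 at -1.15 ± 0.36. Mmp13 had -0.81 ± 0.33 (336 ± 156 to 157 ± 44.1 CPM, edgeR quasi-likelihood with Benjamini-Hochberg, adjusted p = 0.621), Mmp3 -1.51 ± 0.93 (0.621) and Mmp8 0.90 ± 0.55. Without DPBS 4 these became -0.44 for Mmp13, -0.56 for Mmp3 and -0.86 for Adamts4. Over 22 alternatives the median of the list ran from -1.35 without libraries 49 and 50 to -0.37 with the bone score as a term.

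Osteoblast and osteocyte markers fell in 1M (median -0.83, camera adjusted p = 0.000148, adjusted p = 0.592 with an estimated correlation). Its 3 members past when adjusted over the list alone were Phex, Ifitm5 at -1.64 ± 0.45 (35.7 ± 9.86 to 10.4 ± 4.48 CPM) and Bmp3 at -0.52 ± 0.17. Fibrous collagen and fibrosis genes fell with 6 of 6 members lower (median -1.11, camera adjusted p = 0.000903, adjusted p = 0.592 with an estimated correlation), 0 of them adjusted over the list alone. Col5a2 had -1.48 ± 0.58 and Fn1, fibronectin, -0.94 ± 0.93. Endothelial and mural markers fell (median -0.35, camera adjusted p = 0.000929, adjusted p = 0.592 with an estimated correlation), 1 of them, the pericyte gene Rgs5 at -1.20 ± 0.31, adjusted over the list alone. Growth factors fell (median -0.61, camera adjusted p = 0.00139, adjusted p = 0.592 with an estimated correlation), 1 of them, Pdgfb at -0.59 ± 0.11, adjusted over the list alone. Their median was -0.32 without 1M male 1. TGF-beta and BMP genes fell (median -0.48, camera adjusted p = 0.00408, adjusted p = 0.698 with an estimated correlation). WNT genes fell (-0.34, 0.00877, adjusted p = 0.698 with an estimated correlation), as did unfolded protein response genes (-0.20, 0.0490, adjusted p = 0.737 with an estimated correlation). In these 3 lists 0 members passed when adjusted over the list alone. Leaving out 1 library gave medians from -0.69 (without 1M female 2) to -0.29 (without 1M male 1) for TGF-beta and BMP genes. For WNT genes they ran from -0.57 (without 1M female 2) to -0.20 (without 1M male 2). For fibrous collagen and fibrosis genes they ran from -1.48 (without 2M female 1) to -0.70 (without 1M male 1). The unfolded protein response passed in 5 of 12 fits with 1 library left out, with a median of -0.02 without 1M male 2.

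Cartilage matrix genes fell in 1M with 11 of 11 members lower (median -0.67, camera adjusted p = 0.00877, adjusted p = 0.725 with an estimated correlation), 0 of them adjusted over the list alone. The median ran from -1.17 to -0.25 with 1 library left out. Over its 21 alternatives the list passed in 16, and its highest median was -0.056, close to 0. The score of 1M female 2, 10.01, lay above all DPBS libraries (7.96 to 9.01), and the exact permutation p of the score was 0.429. Here Col2a1 had -1.48 ± 0.95 (edgeR quasi-likelihood with Benjamini-Hochberg, adjusted p = 0.621), Acan -0.67 ± 0.86 (0.729), Comp -0.59 ± 0.88 (0.759) and the link protein Hapln1 -0.95 ± 0.86. Hypertrophy genes fell (median -0.25, camera adjusted p = 0.0409, adjusted p = 0.718 with an estimated correlation), with Col10a1 at -0.31 ± 0.81 (0.864), and passed in 8 of 12 fits with 1 library left out (medians -0.53 to -0.14). With the marrow score as a term their median was above 0, at 0.0135. Glycosaminoglycan synthesis genes fell (median -0.38, camera adjusted p = 0.00805, adjusted p = 0.698 with an estimated correlation), to -0.25 without DPBS 4, both lists with 0 members adjusted over the list alone. The inflammatory list (median -0.13, camera adjusted p = 0.385) and the anti-inflammatory list (-0.31, 0.0588) did not pass. Interferon-stimulated genes (0.21, 0.238), erythroid markers (0.44, 0.238), oxidative phosphorylation (0.07, 0.372) and senescence genes (-0.30, 0.326) did not pass either. Il1b had 0.70 ± 0.48 (0.622), Tnf 0.44 ± 0.35 (0.636), Nos2 -0.06 ± 1.18 (0.985), Vegfa -0.16 ± 0.76 (0.927) and Igf1 -0.67 ± 0.23 (0.621). Nos2 had 0.96 and Vegfa 0.44 without 1M male 1, and Col10a1 0.30 without 1M male 2.

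**Figure D3:**
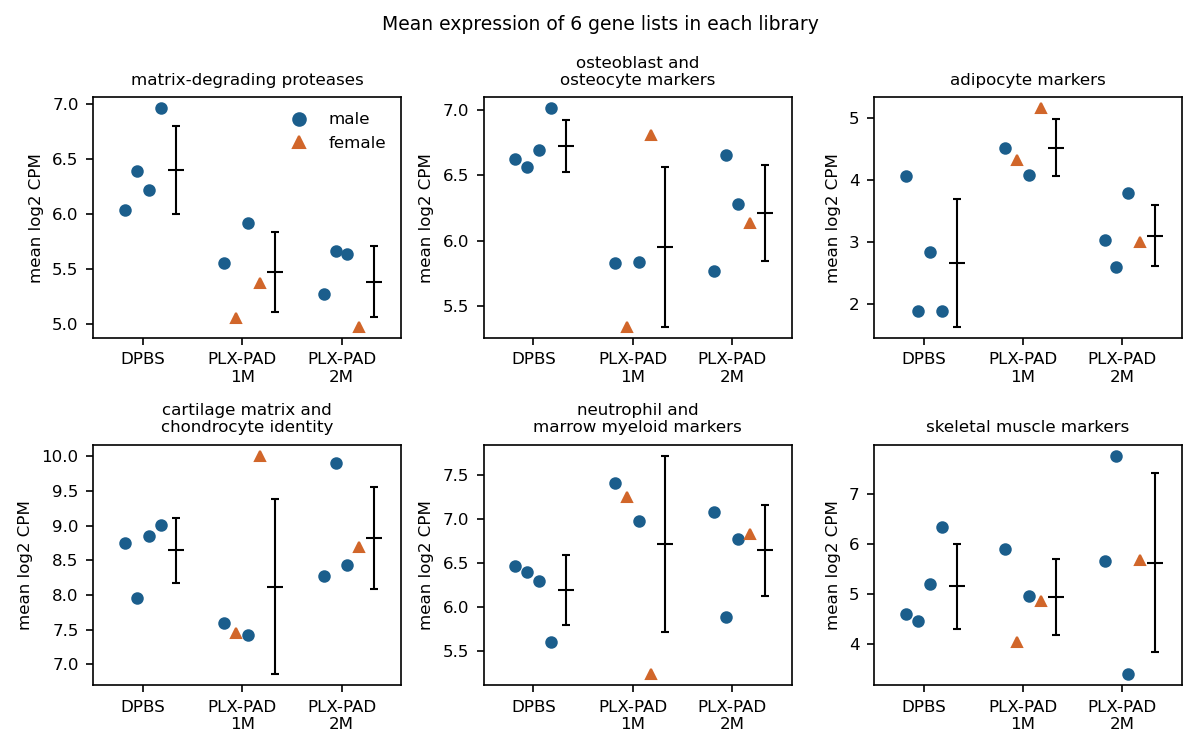
Mean log2 CPM of 6 gene lists in each library by treatment and sex, with mean ± SD (n = 4 per treatment). The protease scores of the 8 treated libraries lie below those of DPBS, and the adipocyte scores of the 4 1M libraries lie above those of DPBS and 2M.

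For the mean of the 1M and 2M groups against DPBS, 4 genes without a symbol passed the test, and the named genes with the smallest p did not. Lamb1 had -0.80 ± 0.11 (edgeR quasi-likelihood with Benjamini-Hochberg, adjusted p = 0.0594) and Pik3c2b -0.59 ± 0.08 (0.0596). Sgms2 had -0.68 ± 0.11 (0.0799), Atp6v0d2 -1.44 ± 0.22 (0.0799) and C1qtnf6, a secreted relative of complement C1q, -1.70 ± 0.27 (0.0799). Above 0 were Hk2 at 0.46 ± 0.10 (0.156), Rap1gap at 0.80 ± 0.18 (0.168), Olfm1 at 0.38 ± 0.09 (0.173), Enosf1 at 0.60 ± 0.14 (0.179) and the membrane-fusion protein Stx3 at 0.59 ± 0.14 (0.203). The genes always named were Adamts4 at -1.54 ± 0.33 (0.156), Igf1 at -0.81 ± 0.19 (0.197), Mmp13 at -1.11 ± 0.27 (0.208) and Mmp3 at -1.45 ± 0.71 (0.562). Mmp13 had -0.74 and Mmp3 -0.49 without DPBS 4. Cartilage genes among them were Col2a1 at -1.10 ± 0.70, Acan at -0.25 ± 0.65, Comp at 0.04 ± 0.66 and Col10a1 at 0.05 ± 0.65. The others were Il1b at 0.64 ± 0.42 (0.628), Tnf at 0.36 ± 0.31, Nos2 at 0.27 ± 0.87 and Vegfa at -0.02 ± 0.59.

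By edgeR quasi-likelihood with Benjamini-Hochberg, 4 genes passed in the mean of the doses against DPBS, all lower and none with a symbol. Leaving out 1 library gave from 0 (without any 1 of 5 libraries) to 139 genes (without 1M female 2). Unadjusted p under 0.05 held for 1,604 genes, 439 higher and 1,165 lower, and DESeq2 called 368 genes (48 higher) and voom with quality weights 2,040 (499 higher). In 7 of 100 groupings of the same libraries voom called as many (highest other 5,606). ENSCPOG00000013899 fell (-1.30 ± 0.13, adjusted p = 0.0211; 21.51 ± 2.995 CPM in DPBS, 6.30 ± 1.84 in 1M and 8.26 ± 2.63 in 2M). ENSCPOG00000003867 fell (-1.54 ± 0.17, adjusted p = 0.0211; 41.8 ± 7.84, 10.7 ± 3.13 and 14.3 ± 4.09 CPM). In males only, without a sex term, 12 genes passed.

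Camera passed 13 of 31 lists for the mean of the doses, 4 higher and 9 lower, while 0 passed with an estimated correlation and fry passed 0. Proteases fell (-0.92, camera adjusted p = 4.8e-07, adjusted p = 0.544 with an estimated correlation), with the same 8 members as in 2M when adjusted over the list alone, among them Ctsk at -1.44 ± 0.24. The protease median was -0.55 without DPBS 4. Osteoblast and osteocyte markers fell (-0.80, 0.000178, adjusted p = 0.600 with an estimated correlation), 5 of them adjusted over the list alone, among them Phex at -0.93 ± 0.15 and Ifitm5 at -1.48 ± 0.35. Endothelial and mural markers fell (-0.42, 0.000510, adjusted p = 0.622 with an estimated correlation), 4 of them (Pdgfrb, Adgrl4, Flt1 and Rgs5) adjusted over the list alone. Growth factors fell (-0.52, 0.000510, adjusted p = 0.600 with an estimated correlation), 3 of them (Pdgfb, Pdgfrb and Igf1). Fibrous collagen and fibrosis genes fell (-0.98, 0.00108, adjusted p = 0.636 with an estimated correlation), 1 of them (Col12a1). WNT genes fell (-0.32, 0.0345, adjusted p = 0.741 with an estimated correlation), 1 of them (Ccn4 at -1.77 ± 0.37). In the other 7 lists 0 members passed when adjusted over the list alone. Lower were anti-inflammatory genes at -0.53 (0.0182, adjusted p = 0.600 with an estimated correlation) and TGF-beta and BMP genes at -0.33 (0.0182, adjusted p = 0.741 with an estimated correlation). Glycosaminoglycan genes lay at -0.29 (0.0202, adjusted p = 0.741 with an estimated correlation), passing in 10 of 12 fits with 1 library left out, and at -0.11 without DPBS 4. Over 21 alternatives they passed in 14, and their highest median was -0.0017, close to 0. Anti-inflammatory genes lay at -0.32 without DPBS 4. Higher were adipocyte markers at 0.77 (0.000474, adjusted p = 0.600 with an estimated correlation) and neutrophil markers at 0.70 (0.0102, adjusted p = 0.741 with an estimated correlation). Proliferation genes lay at 0.39 (0.0345, adjusted p = 0.839 with an estimated correlation) and ribosomal proteins at 0.10 (0.00753, adjusted p = 0.725 with an estimated correlation). With the marrow score as a term the proliferation median was -0.11. Proliferation passed in 8 of 12 fits with 1 library left out (medians 0.23 to 0.55) and WNT genes in 7. Over 21 alternatives WNT genes passed in 11, with a highest median of -0.06. The adipocyte median was 1.33 without DPBS 1 and 0.56 without DPBS 4.

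The protease score, the mean log2 CPM of the protease list in a library, was 6.40 ± 0.40 in DPBS (n = 4) and 5.43 ± 0.32 in the 8 treated libraries. The difference was -0.98 (exact permutation p = 0.00202 over 495 splits, the smallest possible, 0.0626 adjusted over 31 lists). The male libraries alone gave 5.61 ± 0.23 after treatment (exact permutation p = 0.00794). This score test was chosen after the data were examined.

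In 2M against 1M, the lists with the smallest p were fat-cell genes and cartilage matrix genes. The adipocyte list fell with 7 of 7 members lower (median -1.40, camera adjusted p = 1.4e-12, adjusted p = 0.311 with an estimated correlation), 0 of them adjusted over the list alone. Plin1 had -1.66 ± 0.83 (44.0 ± 24.2 to 12.6 ± 7.03 CPM), Dgat2 -1.40 ± 0.45, Adipoq -1.30 ± 0.48 (263 ± 84.2 to 119 ± 49.7 CPM) and Aqp7 -1.07 ± 0.45. Cartilage matrix genes rose with 11 of 11 members higher (median 0.84, camera adjusted p = 1.1e-05, adjusted p = 0.754 with an estimated correlation), 0 of them adjusted over the list alone. Leaving out 1 library gave medians from 0.31 without 2M male 2 to 1.59 without 2M female 1. Cilp had 1.47 ± 0.77, Comp 1.25 ± 0.83, Acan 0.84 ± 0.80 and Col2a1 0.76 ± 0.87. Skeletal muscle markers rose with 11 of 11 members higher (median 1.08, camera adjusted p = 0.0368, adjusted p = 0.822 with an estimated correlation), 0 of them adjusted over the list alone. They passed in 6 of 12 fits with 1 library left out, and the median was 0.12 without 2M male 2, whose score was 7.76. The fast-fibre actinin Actn3 had 1.53 ± 0.72 and the calcium pump Atp2a1 1.49 ± 0.78.

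Camera passed 11 lists in 2M against 1M, 8 higher and 3 lower; 0 passed with an estimated correlation and 0 by fry. Higher were also cholesterol and lipid metabolism at 0.19 (0.000773, adjusted p = 0.311 with an estimated correlation) and the unfolded protein response at 0.21 (0.00319, adjusted p = 0.754 with an estimated correlation). So were TGF-beta and BMP genes at 0.25 (0.0106, adjusted p = 0.754 with an estimated correlation) and WNT genes at 0.28 (0.0143, adjusted p = 0.754 with an estimated correlation). Hypertrophy genes were higher at 0.26 (0.0156, adjusted p = 0.754 with an estimated correlation), as were glycosaminoglycan genes at 0.16 (0.0384, adjusted p = 0.822 with an estimated correlation). Lower were proteases at -0.28 (0.00873, adjusted p = 0.754 with an estimated correlation) and ribosomal proteins at -0.08 (0.0115, adjusted p = 0.754 with an estimated correlation). Glycosaminoglycan genes passed in 7 of 12 fits with 1 library left out, proteases and WNT genes in 8 each, and hypertrophy, TGF-beta and BMP genes and ribosomal proteins in 9 each. Without 2M male 2 the medians were 0.10 for hypertrophy, 0.04 for glycosaminoglycan genes, 0.14 for TGF-beta and BMP genes, 0.13 for WNT genes and 0.09 for the unfolded protein response. Highest were 0.56 and 0.39 for the first 2 (without 2M female 1), and 0.45 for TGF-beta and BMP genes and 0.68 for WNT genes (without 1M female 2). Protease medians ran from -0.35 to -0.17 and ribosomal ones from -0.12 to -0.03.

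By edgeR quasi-likelihood with Benjamini-Hochberg, 0 genes passed between 2M and 1M (smallest adjusted p = 0.883), with 252 at an unadjusted p under 0.05, 66 higher and 186 lower. DESeq2 called 3 and voom with quality weights 0. The named genes all had an adjusted p of 0.997. Above 0 were Olfm1 at 0.43 ± 0.09, Spsb4 at 0.46 ± 0.15, the proton pump Atp12a at 0.89 ± 0.30, the axonal motor Kif1a at 1.69 ± 0.57 and the clock gene Per2 at 1.01 ± 0.39. Below 0 were Cldn1 at -0.85 ± 0.19 (5.88 ± 0.62 to 3.23 ± 0.56 CPM), G0s2 at -0.71 ± 0.22, Dgat2, Abcc12 at -0.54 ± 0.18 and the retinoic acid binder Crabp1 at -0.54 ± 0.19. Mmp13 had -0.59 ± 0.30, Adamts4 -0.45 ± 0.37, Mmp3 0.13 ± 0.83, Il1b -0.11 ± 0.44, Tnf -0.17 ± 0.33, Col10a1 0.71 ± 0.75, Nos2 0.66 ± 1.15, Vegfa 0.28 ± 0.71 and Igf1 -0.28 ± 0.21. Total-count scaling in place of TMM moved the median change of 1M against DPBS by 0.11.

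In females against males, 3 female libraries were compared with 5 male ones within the 2 PLX-PAD groups. The 4 DPBS libraries, all male, add only to the normalisation and the estimate of spread. Kif26b, a kinesin of cell polarity, had 1.84 ± 0.37 (edgeR quasi-likelihood with Benjamini-Hochberg, adjusted p = 0.803). Also above 0 were Galnt15, which starts O-glycan chains, at 2.20 ± 0.46 (0.803), Tbl1x at 0.42 ± 0.08 (0.762), Angptl7 at 2.14 ± 0.49 (0.872) and LOC100726326 at 3.02 ± 0.74 (0.964). Below 0, all with an adjusted p of 0.964, were the pentraxin Ptx3 at -1.11 ± 0.27, Adamts4 at -1.51 ± 0.40, Lamb1 at -0.46 ± 0.13, the PACAP receptor Adcyap1r1 at -1.10 ± 0.32 and Aifm1 at -0.31 ± 0.09. The 1 gene past the threshold, ENSCPOG00000000660, rose by 0.79 ± 0.08 (adjusted p = 0.0471). No gene passed without any 1 of 4 libraries (the 3 female ones and 1M male 2), with total-count scaling or with DESeq2 size factors. At an unadjusted p under 0.05 there were 636 genes, and 48 were called by DESeq2 and 25 by voom with quality weights. The interaction of dose and sex had 0 genes past the threshold by edgeR quasi-likelihood with Benjamini-Hochberg (smallest adjusted p = 0.790), 394 at an unadjusted p under 0.05, 11 by DESeq2 and 0 by voom.

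Camera passed 7 lists in females against males, 3 higher and 4 lower, with 0 passing with an estimated correlation and 0 by fry. Proteases fell (-0.49, camera adjusted p = 0.000165, adjusted p = 0.840 with an estimated correlation), 1 of them, Adamts4, adjusted over the list alone. Oxidative phosphorylation fell (-0.17, 0.000256, adjusted p = 0.840 with an estimated correlation). Cartilage matrix genes rose by 0.95 (0.00337, adjusted p = 0.937 with an estimated correlation). Hypertrophy genes rose by 0.30 (0.0390, adjusted p = 0.937 with an estimated correlation) with 1, Col10a1 at 2.94 ± 0.76, adjusted over the list alone. TGF-beta and BMP genes rose by 0.28 (0.0418, adjusted p = 0.937 with an estimated correlation). Proliferation fell (-0.33, 0.00337, adjusted p = 0.937 with an estimated correlation), as did erythroid markers (-0.37, 0.0313, adjusted p = 0.937 with an estimated correlation). The cartilage, hypertrophy, TGF-beta and BMP, erythroid and proliferation medians changed sign without 1M female 2. Oxidative phosphorylation ran from -0.29 (without 2M female 1) to -0.08 (without 1M male 1).

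The 1M and 2M groups shared 0 genes past the threshold by edgeR quasi-likelihood with Benjamini-Hochberg, and 102 by DESeq2, where 2.04 would be expected if independent. Since both used the same 4 DPBS libraries, their changes are related by design. Over all genes their covariance was 0.202, against 0.0242 (0.0194 to 0.0275) in 20 simulations of unchanged groups with those controls. The simulated groups were drawn around the mean of those same DPBS libraries, so they leave out the covariance that shared controls give. They therefore cannot show how much of the 0.202 comes from the shared controls. With the DPBS libraries split 2 and 2 between the doses the mean covariance was 0.107 and 70.9% of genes had the same sign, against 81.5% with shared controls. Pdgfb (-0.59 ± 0.11 in 1M, -0.59 ± 0.10 in 2M), Ctsk (-1.21 ± 0.29, -1.67 ± 0.26), Adamts4 (-1.32 ± 0.41, -1.77 ± 0.36) and Ccn4 (-1.72 ± 0.47, -1.83 ± 0.41) lay lower at both doses.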

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

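The marrow score, the bone score, the neutrophil and erythroid scores as a test of marrow, the removal by haemoglobin and the permutations of list scores were chosen only after the results were seen.

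The protease list was lower after PLX-PAD at both doses, with adjusted p = 0.592 in 1M, 0.214 in 2M and 0.544 for the mean with an estimated correlation. For the mean of both doses against DPBS, 3 other explanations were tested. In male libraries only the protease median was -1.02, which rules out the sex imbalance of the DPBS group. The median over all libraries, -0.92, was -0.55 without DPBS 4. With the marrow score as a term it was -0.66 and with the bone score as a term -0.57, so a part played by marrow or bone content stays open. Ctsk, Adamts4, Mmp13 and Mmp14 lay lower in all 8 treated libraries than in all 4 DPBS libraries. Whether the fall is a change within cartilage or a smaller share of bone in the samples cannot be told from these counts.

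Adipocyte genes such as Plin1, Adipoq and Dgat2 lay higher in 1M than in 2M (list adjusted p = 0.311 with an estimated correlation). When 1 of the 1M libraries was left out in turn, the median of 2M against 1M nearest to 0 was -1.09 (without 1M female 2), which rules out fat in a single library. More fat tissue taken along in all 4 1M samples was not tested and stays open.

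Blood and marrow genes varied between libraries of 1 treatment. The neutrophil score followed the erythroid score (Pearson r = 0.891, 0.731 without the 2 farthest libraries). Marrow carried into the samples in varying amounts would give this, but so would blood cells varying within the tissue, so it stays open. Its correlation with the total count was -0.0103 over the 12 libraries and -0.433 without the 2 farthest, both nearer 0 than the 0.5 set beforehand. 1M female 1 and 1M female 2 had totals of 82,883,896 and 82,374,977 but neutrophil scores of 7.24 and 5.24, so sequencing depth is ruled out as the source of that difference. A part of the treatment was not excluded, since the neutrophil list passed at 1M (camera adjusted p = 0.00877, adjusted p = 0.718 with an estimated correlation) and at 2M (0.0263, adjusted p = 0.870 with an estimated correlation).

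The real groups were set beside other groupings of the same libraries. For edgeR genes in 2M against DPBS only the real grouping reached its count, 1 of 35 (real 6, highest other 0). That is the smallest share possible and 1 of 10 such counts, not adjusted for their number. The 6 genes also became 0 when any 1 of 10 libraries was left out, so chance is not excluded. For the mean of the doses the share was 2 of 100 for the edgeR genes (real 4, highest other 99). For the voom genes it was 7 of 100 (real 2040, highest other 5606). The edgeR share is again 1 of 10 counts, and chance is not excluded for either. Leaving out 1 library gave 0 to 139 edgeR genes for the mean, and 0 without any 1 of 5 libraries. Where the real count was 0 every grouping reaches it, so nothing is decided for edgeR genes in 1M against DPBS (35 of 35, highest other 1) or in 2M against 1M (35 of 35, highest other 1679). Chance cannot be excluded for genes in females against males (real 1, highest other 6582; 4 of 56). It cannot be excluded for the number of lists in 1M against DPBS (real 15, highest other 21; 7 of 35), 2M against DPBS (real 8, highest other 18; 19 of 35), 2M against 1M (real 11, highest other 16; 14 of 35), the mean of the doses (real 13, highest other 19; 26 of 100) or females against males (real 7, highest other 19; 40 of 56). Groupings that called many genes, such as the 6582 called with 1M male 1, 1M female 1 and 1M male 2 as 1 group, point to a structure of the samples, and what sets it was not tested. With voom the shares were 4 of 35 in 1M against DPBS (real 3093, highest other 6430), 1 of 35 in 2M against DPBS (real 394, highest other 1) and 16 of 56 in females against males (real 25, highest other 10811).

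Without the library of lowest haemoglobin in each treatment (DPBS 4, 1M female 2 and 2M male 2), the counts of genes past the threshold were 4087 in 1M, 117 in 2M, 163 in 2M against 1M and 2804 in the mean of the doses. Among the 63 other ways of leaving out 1 library per treatment the highest counts were 4295, 1, 453 and 3286, and the median was 0. This removal was chosen after the libraries were seen to stand apart, so its counts are not used as results. Voom gave the same 3 libraries the lowest weights, 0.0891 for 1M female 2, 0.286 for 2M male 2 and 0.402 for DPBS 4.

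Of 243 groups of 4 values searched for a library far from the others, 20 held one, where chance would flag about 1 in 20, or 12.15. The log2 CPM values were Comp in 1M female 2 (14.32, highest), Col10a1 in DPBS 1 (4.52, highest), Mmp3 in 2M male 2 (4.75, highest), Adamts4 in 2M female 1 (1.00, lowest), Il1b in 2M male 2 (3.51, lowest), Igf1 in DPBS 4 (6.98, highest), Ctsk in 2M female 1 (7.91, lowest), Stx3 in DPBS 4 (5.14, lowest) and C1qtnf6 in DPBS 4 (8.06, highest). The score values were, in 1M female 2, cartilage matrix (10.01, highest), glycosaminoglycan (6.11, highest), TGF-beta and BMP (6.11, highest) and proliferation (4.44, lowest). In 2M male 2 they were glycosaminoglycan (5.98, highest), erythroid (7.02, lowest), WNT (4.76, highest) and proliferation (5.44, lowest), in DPBS 4 nerve (1.00, lowest) and in 1M male 1 ribosomal (8.95, highest). The share of counts in genes without a symbol was lowest in 1M female 2 (54.1%). Of the 20, 6 were in 1M female 2 and 6 in 2M male 2.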

How the results depend on the processing

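The fits with a marrow term and without the lowest-haemoglobin libraries were chosen only after the results were seen. No pairing across treatments by the numbers in the sample names was seen (5 of 13 same-numbered pairs with a correlation over 0.1, range -0.449 to 0.706). A block for them was therefore fitted only as an alternative. Groups of 2 libraries gave exact opposites, such as 0.666 for 1M female 1 and -0.666 for 1M female 2 with 2M male 1. The check therefore cannot exclude a pairing. For every move below the cause was not tested.

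Genes past the threshold in 1M against DPBS moved from 0 to 161 with DESeq2, 3093 with voom quality weights, 6 without a sex term, 2 with total counts, 1 with the block, 1 without libraries 49 and 50, 43 with a marrow term and 4087 without the lowest-haemoglobin libraries. With 1 library left out the range was 0 to 61, decided by 1M female 2.

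In 2M against DPBS the count of 6 moved to 283 with DESeq2, 394 with voom quality weights, 23 at a threshold of 0.1, 11 with total counts, 3 with the block, 1 without libraries 49 and 50, 193 with a marrow term and 117 without the lowest-haemoglobin libraries. It was 0 without a sex term, in males only and with only the 2 groups compared. With 1 library left out the range was 0 to 6: 6 without 1M female 2, 2 without DPBS 4 and 0 without any other.

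For 2M against 1M the count of 0 moved to 3 with DESeq2 and 163 without the lowest-haemoglobin libraries. For the mean of the doses the count of 4 moved to 368 with DESeq2, 2040 with voom quality weights, 42 at a threshold of 0.1, 14 with total counts, 10 with a minimum count of 50, 179 without a sex term, 12 in males only, 25 without libraries 49 and 50, 184 with a marrow term and 2804 without the lowest-haemoglobin libraries. With 1 library left out the range was 0 to 139: 139 without 1M female 2, 10 without 2M male 2, 1 without DPBS 4, 1M female 1 or 1M male 2, and 0 without DPBS 2, DPBS 3, 1M male 1, 2M male 1 or 2M male 3.

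For females against males the count of 1 moved to 48 with DESeq2, 25 with voom quality weights, 2 without a filter, 39 with a marrow term and 2 without the lowest-haemoglobin libraries. It was 0 with DESeq2 size factors, total counts, the block, only the 2 doses compared, and without libraries 49 and 50. With 1 library left out the range was 0 to 2: 2 without DPBS 4, and 0 without 1M female 1, 1M female 2, 1M male 2 or 2M female 1. The interaction moved from 0 to 11 with DESeq2, 6 with a marrow term, 1 without libraries 49 and 50 and 1 without 1M male 1 or 1M male 2 (range 0 to 1). The overlap of the doses moved from 0 to 102 with DESeq2 and 5 without 1M female 2 (range 0 to 5).

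The count of lists past the threshold fell to 0 in all 5 contrasts with an estimated correlation, and with fry to 0 in all but 2M against DPBS, where it was 1. With 1 library left out the range was 9 to 16 in 1M against DPBS (9 without 1M male 2), 7 to 14 in 2M against DPBS (14 without 2M male 2) and 2 to 10 in females against males (2 without 1M male 2). In 2M against 1M it was 4 to 16 (4 without 2M male 2, 5 without 1M male 2, 6 without 1M female 1), and 7 lists passed without a sex term.

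The direction of a list turned in 13 fits, and medians changed sign in 15, 3 of them without a turned direction. These 3 were hypoxia and glycolysis in 2M against DPBS without 2M male 2 (-0.06) and, with a marrow term, hypertrophy in 1M against DPBS (0.0135) and in females against males (-0.03). With a marrow term proliferation became -0.11 in 1M against DPBS and -0.11 in the mean of the doses, and TGF-beta and BMP genes turned direction in females against males at a median of 0.0240. In females against males without libraries 49 and 50 the medians were -0.25 for cartilage matrix, -0.20 for hypertrophy, 0.20 for erythroid markers, -0.13 for TGF-beta and BMP genes, and 0.14 for proliferation. With 1 library left out they ran from -0.16 to 1.72 for cartilage matrix, -0.13 to 0.81 for hypertrophy, -0.95 to 0.0697 for erythroid markers, -0.14 to 0.48 for TGF-beta and BMP genes and -0.78 to 0.0941 for proliferation, the reversed end without 1M female 2 and the other without 2M female 1. In the reported model they were 0.55, 0.39, 0.95, 0.30, -0.37, 0.28 and -0.33.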

Other observations

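The scores of osteoclast markers (of the cells that resorb bone and calcified cartilage) and of macrophage markers were lower after PLX-PAD, though not every member was. Only 4 of 17 osteoclast markers and 4 of 26 macrophage markers had a row, too few for the list test. Both lists were permuted only after the results were seen. The osteoclast score was 7.14 ± 0.32 in DPBS (n = 4) and 6.17 ± 0.21 in the 8 treated libraries (exact permutation p = 0.00202, 0.0121 adjusted over 6 lists; two-sided). In male libraries alone the exact permutation p was 0.00794 (0.0476 adjusted). Its members were Ctsk (also in the protease list), Atp6v0d2, Clcn7 and Nfatc1. The chloride exchanger Clcn7 had -0.28 ± 0.10 in 1M and -0.33 ± 0.10 in 2M and the osteoclast transcription factor Nfatc1 -0.55 ± 0.23 and -0.19 ± 0.20. The macrophage score was 5.36 ± 0.30 in DPBS and 4.87 ± 0.23 after treatment (exact permutation p = 0.00808, 0.0242 adjusted, and in males 0.0556, 0.111 adjusted). In it the scavenger receptor Marco had -1.53 ± 0.56 in 1M and -2.24 ± 0.52 in 2M (6.79 ± 4.08, 2.81 ± 1.47 and 1.57 ± 0.34 CPM in DPBS, 1M and 2M) and the chemokine receptor Cx3cr1 -0.22 ± 0.16 and -0.45 ± 0.15. The mannose receptor Mrc1 had 0.02 ± 0.22 and -0.25 ± 0.21 and Laptm5 0.27 ± 0.36 and 0.24 ± 0.34, so the score did not move as 1 block.

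The synovial sublining score was 8.85 ± 0.11 in DPBS and 8.44 ± 0.33 after treatment (exact permutation p = 0.0485, 0.0970 adjusted), with Cd34 at -0.71 ± 0.22 in 1M and -0.59 ± 0.19 in 2M. Superficial zone genes (5.86 ± 0.21 and 5.67 ± 0.76; exact permutation p = 0.653), antigen presentation (4.84 ± 0.44 and 5.13 ± 0.31; 0.214) and protease inhibitors (6.37 ± 0.23 and 6.15 ± 0.81; 0.602) did not pass. Masp1, the 1 complement gene with a symbol, had -0.34 ± 0.31 in 1M and -0.77 ± 0.27 in 2M. The cell-cycle gene Ccnd1 had -0.77 ± 0.25 and -0.59 ± 0.22. Skeletal muscle scores spread from 3.40 to 7.76 within 2M, against 5.15 ± 0.85 in DPBS and 4.94 ± 0.76 in 1M.

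In all 8 treated libraries 433 genes lay below all 4 DPBS libraries and 101 lay above them, where 34.2 (0.202%) would be expected per direction. A split of the 12 libraries into 4 and 8 gave as many in 9 of 495 cases (exact permutation p = 0.0182), and the highest other split gave 3799. In males 676 lay below and 218 above, where 134 (0.794%) would be expected per direction (exact permutation p = 0.0476). Lower were Lamb1, Ctsk, Mmp13, Mmp14, Adamts4, Igf1, Pdgfb, Panx3 and Tnfsf11, and higher were Hk2, Enosf1, Rap1gap, Stx3 and Erg. Erg, an endothelial and joint-surface transcription factor, had 0.35 ± 0.21 in 1M and 0.48 ± 0.19 in 2M.

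Osteoblast scores followed the scores of fibrous collagen and fibrosis genes over the 12 libraries (Pearson r = 0.921, Spearman rho = 0.923). Without the 2 farthest libraries r was 0.893. Protease scores followed osteoblast scores less closely (r = 0.657, permutation p = 0.021, adjusted 0.025, and rho = 0.622, permutation p = 0.034, adjusted 0.041). There r was 0.513 without the 2 farthest, and these were 2 of 6 relations. Mean osteoblast scores were 6.72 in DPBS, 5.95 in 1M and 6.21 in 2M, and mean protease scores 6.40, 5.47 and 5.38. Fibrous collagen and fibrosis scores were also lower at both doses (11.58, 10.16 and 10.66). Part of each r over all libraries can thus come from the difference between treatments. Relations within a treatment were not tested. Histology, protein levels and joint scores were not analysed here.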
